A study of Schizosaccharomyces pombe with 88 samples.

How the data were processed

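The measurements were total RNA levels of synchronous fission yeast cultures on 88 two-colour arrays. Per the labels, sample cDNA carried Cy5 and was hybridised against Cy3-labelled cDNA of asynchronous untreated wild-type cells from mid-log culture, which served as the common reference on every array. Samples were grouped from the array titles by strain (WT, rad3, cds1, chk1), arm (0 min start, untreated, or 8 mM hydroxyurea, HU) and time. The titles numbered 2 array repeats for each of the 44 conditions, which the series text names technical repeats. The labels name no replicate cultures, so p-values measure only the spread between these samples (conditions of 1 culture per strain and treatment), which may be technical, and strain cannot be told from culture or array batch.

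The deposited value table holds log2 ratios of sample over reference, and no scanner values were used here. The log2 scale was read from the values: 99.678% of them are the log2 of a ratio with 3 decimals, to within 0.01 of a thousandth. The direction followed the dyes named per the labels and was checked on the mutated genes, whose values lay far below 0 on arrays of the rad3 and cds1 mutants. Background correction, within-array normalization, centring and spot filters are not given in the sources used here, so whether each array was scaled to the same spread stays unknown. The table is 99.401% complete. The SD over probes ran from 0.772 to 0.944 on the 8 arrays of 0 min (median 0.846) and from 0.342 to 0.709 on the other 80 (median 0.473). The lowest correlation between any 2 arrays over probes was -0.22. Median log2 ratios lay within 0.1 of 0 except on 5 arrays, namely rad3 untreated at 160 min, repeat 1 (-0.15), chk1 untreated at 120 min, repeats 1 (-0.23) and 2 (-0.11), chk1 with HU at 120 min, repeat 1 (-0.14), and chk1 with HU at 200 min, repeat 1 (-0.18). Depth has no meaning for arrays, and their number limits the precision.

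Gene names came from the platform annotation. Of 9858 probes, 9632 had 1 gene symbol, 44 had several and 182 had none. Symbols of 9582 probes were updated through a gene table of the ASM294v3 assembly, used for names only. Probes with a value on fewer than 80% of the arrays were left out (35 probes). Probes of the same gene were averaged, giving 4929 units, 4815 of them with a single gene name, and 4928 were tested. Over genes the median correlation between the 2 probes of a gene across arrays was 0.506, and 8.60% of genes had probes that correlated below 0.

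Array repeats were averaged to 1 value per condition. Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. For HU, the difference of treated minus untreated at the same strain and time was the unit (20 differences), and strain means of these differences were tested with 16 residual degrees of freedom. A late (120, 160 and 200 min) minus early (40 and 80 min) contrast in WT had 12. The 24 conditions without HU were fitted with strain and time terms (15 residual degrees of freedom), giving a moderated F test over time and contrasts of each mutant with WT. These tests, the gene lists, the rule for named genes and the alternatives on this design were fixed before the data were examined. A further fit by time point was chosen after the planned results were seen. It estimated the HU difference at each time in WT and chk1, in rad3 and cds1, and the difference between these pairs, with 8 residual degrees of freedom. It left out 6 arrays labelled chk1 that match WT arrays, so that WT stands alone at 120 and 200 min.

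The gene lists were MBF targets (genes of the G1/S transcription factor MBF), core histones, mitosis and septation genes, DNA replication factors, checkpoint factors, DNA repair, dNTP supply, environmental stress response, redox defence, iron uptake, iron-using proteins, ribosomal proteins, ribosome biogenesis, chaperones, mating and meiosis, glycolysis and fermentation, proteasome, and auxotrophic marker genes. A further list fixed beforehand entered the adjustment over lists and the totals of list results and is not reported here. The MBF target yox1 was not found among the measured symbols. Lists share members: 7 of the 18 measured MBF targets also stand in other lists. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. Counts of called members are given over all genes tested and adjusted over the list alone. Named genes were, in each comparison, the 10 with the largest rise and the 10 with the largest fall among called genes of one sign at all matched points, up to 4 members of each list with the largest absolute change, and rad3, cds1, chk1, cdc22, suc22, cdc18, cdt1, cig2, mik1, nrm1, spd1, hht2, hta1, cdc15, plo1, eng1 and ura4. For the time course they were the 20 genes with the largest range of time means.

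Alternatives were each array as a sample without a block, with the array repeat number as a replicate block, or with the condition as a random block; each repeat, time point or strain left out; arrays centred on their medians; quantile normalization between arrays; other limits on missing values; eBayes with trend and robust settings; the spread from the compared strains alone; late time points alone; 0 min left out; and the 5 arrays with shifted medians, or the 6 matching arrays, left out or put back. No scaling moved the median change of all genes by over 0.1. The steps were tested on simulated data built on 4919 genes, of which 200 were changed. For the mean HU effect in WT, 92.5% of genes changed by 0.5 and 98.5% of genes changed by 1 on the log2 scale were recovered, with 9 false calls. For the HU effect at 160 min in WT and chk1 these shares were 67.2% and 95.5% with 11 false calls, and at 200 min in WT 29.9% and 83.6% with 5. For the difference between the strain pairs at 160 min they were 23.9% and 86.6% with 6. In the simulation of the mean HU effect the change was equal at all 5 times. Its spread was that of the fit by time point. The shares for the mean effect therefore do not hold for effects that vary over time. In the real data the mean HU effect on cdc22 in WT, 1.70 ± 0.59, did not pass limma's test (adjusted p = 0.56). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.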

Results

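Cells of Schizosaccharomyces pombe were made synchronous by elutriation, which selects small cells in early G2, and were followed for 200 min with or without 8 mM hydroxyurea (HU), an inhibitor of ribonucleotide reductase that starves cells of deoxynucleotides and stalls DNA replication. The strains were wild type (WT) and mutants of rad3 (the ATR-family checkpoint kinase), cds1 (the effector kinase of the replication checkpoint) and chk1 (the effector kinase of the DNA damage checkpoint). RNA was sampled at 0 min and at 40, 80, 120, 160 and 200 min of each arm, which gave 44 conditions with 2 array repeats each. Values are log2 ratios against a common reference of asynchronous untreated WT cells, with ± as SE unless SD is named. Repeats correlated over probes with a median r of 0.701 in WT, 0.786 in rad3, 0.976 in cds1 and 0.986 in chk1. The 2 repeats of chk1 with HU at 160 min were nearly identical (77.1% of values equal, r = 0.9992), so each condition counted once.

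The mutated genes were read first on all arrays of each strain. The 2 probes of cds1 averaged -3.75 ± 0.28 and -2.13 ± 0.18 (SD, n = 22 arrays) in the cds1 strain against 0.33 and 0.38 in WT. The 2 probes of rad3 averaged -2.88 ± 0.37 and -2.52 ± 0.63 (SD, n = 22) in the rad3 strain against -0.43 and -0.48 in WT. The chk1 probes averaged -1.61 ± 0.52 (SD, n = 21) and -0.63 ± 0.23 (SD, n = 22) on arrays labelled chk1 against -0.50 and -0.21 in WT. On 6 of the arrays labelled chk1, those of 120 min in both arms and of HU at 200 min, the values lay unusually close to the WT arrays of the same arm, time and repeat. The second repeats differed from their WT counterparts with an SD of 0.00594, 0.00188 and 0.00497 around a constant offset, where the lowest SD between any other arrays of different strains was 0.238. The first repeats differed more, with an SD of 0.184, 0.129 and 0.110 (r = 0.926, 0.941 and 0.976, where the highest r of other such pairs after 0 min was 0.819). These conditions were therefore counted once, under the WT label, in all values by time point, and chk1 has no HU difference of its own at 120 and 200 min here.

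Without HU, the G1/S genes and histones went through a wave that had its highest list means at 80 or 120 min in WT, rad3 and cds1. cdc22, the large subunit of ribonucleotide reductase, climbed from -3.38 ± 0.22 at 0 min to 0.96 ± 0.46 at 120 min and was back at -2.31 ± 0.75 at 160 min (mean ± SD over strains, n = 4, or 3 at 120 min). cdc18, a licensing factor for DNA replication, went from -2.16 ± 0.30 at 0 min to 0.94 ± 0.42 at 80 min. The histone H2A gene hta1 went from -2.04 ± 0.12 at 40 min to 1.59 ± 0.33 at 120 min. slp1, an activator of the anaphase-promoting complex, and plo1, the Polo kinase, were highest at 80 min with 1.61 ± 0.52 and 0.82 ± 0.15, ahead of eng1, a glucanase that splits the septum, at 120 min with 0.93 ± 0.33. spd1, an inhibitor of ribonucleotide reductase, ran the opposite way, with 1.35 ± 0.13 at 0 min, -0.91 ± 0.31 at 80 min and 0.70 ± 0.14 at 160 min.

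Stress genes stood far above the reference at the start and fell within the first 40 min. The 22 genes of the environmental stress list averaged 2.68 in WT, 2.66 in rad3, 2.83 in cds1 and 2.65 in chk1 at 0 min, and 0.23, 0.85, 0.69 and 0.18 at 40 min. hsp9, a small heat shock protein, went from 4.40 ± 0.22 at 0 min to -0.37 ± 1.06 at 80 min (SD, n = 4). gpd1, which makes glycerol for osmotic protection, went from 3.31 ± 0.53 to -0.57 ± 0.72, and the catalase gene ctt1 from 2.35 ± 0.10 to -0.44 ± 0.30. Wide ranges of the time means were those of SPOM_SPACUNK4.17 (6.41), lsd90 (5.80) and dut1, the dUTPase (4.87). The copper transporter gene ctr4 was at -3.94 ± 0.41 at 0 min and at 0.40 ± 0.28 at 120 min. Ribosomal protein genes averaged -0.32 at 0 min and 0.64 at 40 min in WT.

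The moderated F test of limma called 3952 of 4928 genes changed over the 6 time points, with each strain as 1 replicate. The untreated 120 min condition labelled chk1, which matches WT arrays, entered this planned test as a replicate of its own. Without the 0 min conditions the count was 2516. Of the called genes, 1528 had their highest mean at 0 min, 675 at 40 min, 669 at 80 min, 517 at 120 min, 241 at 160 min and 322 at 200 min. Among the lists, the test called 18 of 18 MBF targets, 9 of 9 core histones and 18 of 19 mitosis and septation genes. It called 34 of 37 DNA replication factors, 27 of 30 DNA repair genes, 8 of 8 dNTP supply genes, 21 of 22 stress genes, 115 of 117 ribosomal proteins, 14 of 14 ribosome biogenesis genes and 13 of 13 glycolysis genes. It called 7 of 13 checkpoint factors, 12 of 23 mating and meiosis genes, 9 of 12 redox defence genes and 7 of 10 iron-using proteins. The remaining lists gave 10 of 11 iron uptake genes, 11 of 13 chaperones, 23 of 26 proteasome genes and 6 of 6 marker genes. Adjusted over the list alone, the counts differed for checkpoint factors (6) and mating and meiosis (10).

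**Figure D1:**
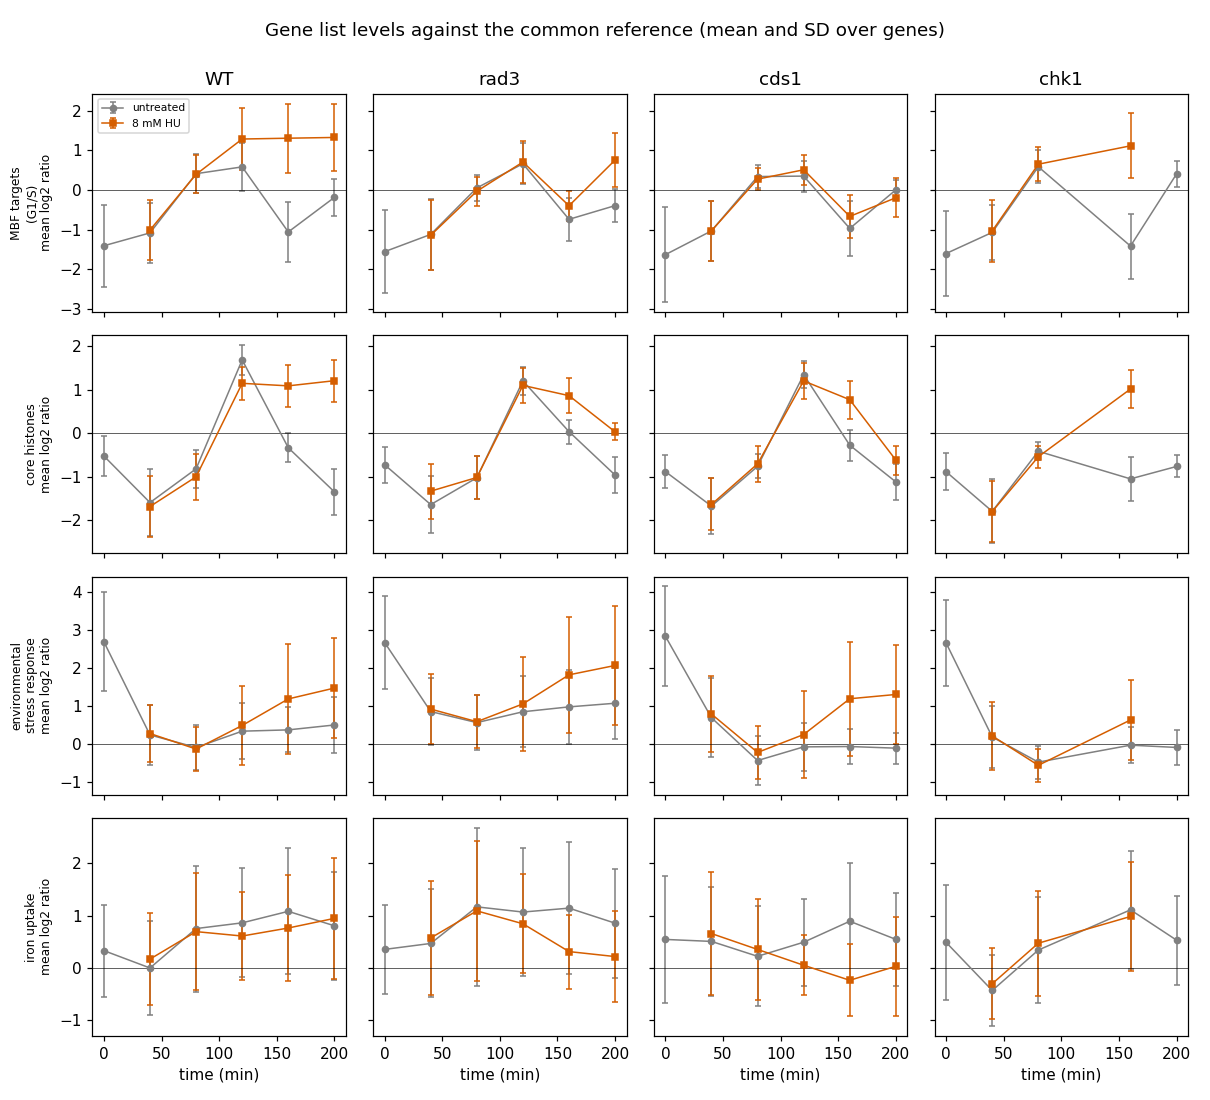
Mean log2 ratio against the common reference (vertical axis) by time in min (horizontal axis) for 4 gene lists (rows) in 4 strains (columns), with bars for the SD over genes; grey circles are untreated conditions with the 0 min start, orange squares are 8 mM HU, and conditions of chk1 that match WT arrays are omitted. The MBF targets with HU at 160 min lie at 1.30 in WT and 1.11 in chk1 against -0.40 in rad3 and -0.67 in cds1; the iron uptake mean of WT at 200 min is higher with HU as deposited (0.14) and lower after quantile normalization (-0.21).

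Averaged over the 5 matched times, HU raised the G1/S list in WT and in the conditions labelled chk1, whose HU arrays at 120 and 200 min match WT arrays. MBF targets averaged 0.93 above untreated in WT (camera, adjusted p = 3.8e-17) and 0.85 in chk1 (adjusted p = 1.6e-10). Of the 18, 16 and 11 passed adjusted over the list alone, with 0 over all genes. Neither list call held with an estimated correlation (adjusted p = 0.30 in WT and adjusted p = 0.56 in chk1). In rad3 and cds1 the list means were 0.29 and 0.04 (adjusted p = 0.15 and 0.95). The direct contrasts of MBF targets gave -0.64 for rad3 minus WT (adjusted p = 6.8e-08, and adjusted p = 0.70 with an estimated correlation) and -0.89 for cds1 minus WT (adjusted p = 6.8e-13, and adjusted p = 0.46 with an estimated correlation). Environmental stress genes averaged 0.39 higher in WT, 0.43 in rad3, 0.66 in cds1 and 0.47 in chk1 (adjusted p = 0.00025, 7.0e-04, 6.1e-08 and 6.1e-05; adjusted p = 0.60, 0.69, 0.59 and 0.56 with an estimated correlation). Core histones averaged 0.63 higher in WT and 0.67 in chk1 (adjusted p = 0.0014 and 0.0027; adjusted p = 0.60 and 0.56 with an estimated correlation). Iron uptake genes averaged -0.33 in rad3 and -0.36 in cds1 (adjusted p = 0.0073 and 0.009; adjusted p = 0.69 and 0.62 with an estimated correlation). In cds1, 14 of the 22 stress genes and 7 of the 13 chaperones passed adjusted over the list alone, and 0 over all genes.

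With the settings chosen beforehand these averages over time called no single gene, but some counts moved with other settings. limma called 0 genes for the mean HU effect in WT (440 at an unadjusted p under 0.05), 0 in rad3 (796), 0 in cds1 (1061) and 0 in chk1 (729). It called 0 for rad3 minus WT (239), cds1 minus WT (163), chk1 minus WT (50) and rad3 and cds1 minus WT and chk1 (429). In chk1 minus WT the matching arrays stand on both sides, which by construction brings the difference nearer to 0. Its counts therefore do not show that chk1 responded to HU like WT. The contrast of the pairs counts the matching arrays under both WT and chk1. Without repeat 2 the count in rad3 was 133, and after quantile normalization that in cds1 was 28. With only the late times the counts were 10 in WT, 140 in rad3, 651 in cds1 and 28 in chk1, where the HU arrays of 2 of the 3 late times match WT arrays. Without the matching arrays the mean HU effect in chk1 called 0 genes by limma (458 at an unadjusted p under 0.05). With each technical array as a sample they were 197, 759, 1100 and 580, and the last contrast gave 155. Late minus early in WT called 1 gene, rev1, a translesion DNA polymerase, which rose by 2.25 ± 0.29 (adjusted p = 0.0024, n = 3 late and 2 early times). That contrast called 0 genes without 40 min (115 at an unadjusted p under 0.05), 0 without repeat 2 (303), 6 without repeat 1, 2 without 160 min, 2 without 200 min, 225 without 120 min, and 6 without the matching arrays.

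Taken by time point, a division chosen after these results were seen, HU left few traces at 40 and 80 min. limma called 0 genes in WT and chk1 at 40 min (275 at an unadjusted p under 0.05) and 80 min (294), and 0 in rad3 and cds1 at 40 min (550) and 80 min (199). With arrays as samples and a replicate block the counts were 1, 3, 20 and 0. Without chk1, WT alone gave 4 at 40 min, and rad3 and cds1 gave 21 at 40 min without repeat 1. MBF targets differed by 0.07 and -0.02 at these times in WT. The difference between rad3 and cds1 on one side and WT and chk1 on the other called 2 genes at 40 min, mde7, a meiosis gene, at -1.85 ± 0.30 (adjusted p = 0.043) and SPOM_SPBC16G5.19 at -1.19 ± 0.14. Without repeat 1, repeat 2, rad3 or cds1 that count was 0 (528, 122, 293 and 405 at an unadjusted p under 0.05 by limma), 1 without WT and 5 without chk1.

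At 120 min in WT the first genes passed the test. hsp16, a small heat shock protein, rose by 2.25 ± 0.36 (adjusted p = 0.023). cdt2, an MBF target that directs degradation of Spd1 and Cdt1, rose by 1.71 ± 0.28 (adjusted p = 0.023), and ams2, an MBF target and histone gene activator, by 1.25 ± 0.20. The stress transcription factor gene atf1 fell by 1.25 ± 0.16 (adjusted p = 0.0047). Of the MBF targets 2 of 18 passed (3 adjusted over the list alone), with a list mean of 0.70 (adjusted p = 6.8e-11, and adjusted p = 0.33 with an estimated correlation). cdc18 at 1.47 ± 0.38 and cdc22 at 0.90 ± 0.56 did not pass. Histones lay at -0.54 (adjusted p = 9.3e-08, and adjusted p = 0.33 with an estimated correlation), with 0 of 9 past the test over all genes and 4 lower adjusted over the list alone. In all, 11 genes were higher and 5 lower, n = 1 strain with the spread taken from the other strains. The count was 1 with trend and robust settings, 4 without the arrays of shifted median, 6 after quantile normalization, 9 without repeat 1, 7 without repeat 2, 7 without chk1, which ended the call of ams2, and 375 with the matching chk1 arrays put back.

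At 160 min with HU, the cultures labelled WT and chk1 held the G1/S program far above the untreated cultures. cdc22 was 4.63 ± 0.39 higher (adjusted p = 1.0e-06, n = 2 strains), cdc18 4.23 ± 0.27 (adjusted p = 6.6e-08), tos4, a chromatin-binding MBF target, 4.08 ± 0.33, and cdt2 3.61 ± 0.20. The S-phase cyclin gene cig2 rose by 3.57 ± 0.20, the replication licensing gene cdt1 by 3.36 ± 0.39, dut1 by 3.23 ± 0.34 and mik1, a kinase that restrains mitosis, by 3.14 ± 0.38. Of the 18 MBF targets 17 rose (18 adjusted over the list alone), with a mean of 2.45 (adjusted p = 2.5e-24, and adjusted p = 0.051 with an estimated correlation). The remaining target suc22, the small subunit of ribonucleotide reductase, was at 0.26 ± 0.10 (adjusted p = 0.088). nrm1, the repressor that shuts MBF targets off, rose by 1.65 ± 0.16. spd1 fell by 1.31 ± 0.13 (adjusted p = 6.3e-06).

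Histone genes rose with them. Of the 9, 8 passed (8 adjusted over the list alone), with a mean of 1.74 (adjusted p = 3.6e-13, and adjusted p = 0.056 with an estimated correlation). The H4 genes hhf1 and hhf3 were 2.43 ± 0.20 and 2.36 ± 0.17 higher, hta1 2.04 ± 0.18, and hht2 did not pass (0.12 ± 0.10). In DNA metabolism single genes moved both ways. mrc1, a mediator of the replication checkpoint, rose by 2.34 ± 0.24, the replication protein A gene ssb1 by 1.52 ± 0.20, rad54 of homologous recombination by 1.42 ± 0.13 and ctp1 of break resection by 1.36 ± 0.11. mcm3 of the replicative helicase fell by 1.04 ± 0.10 and rad16 by 1.34 ± 0.16. Of 37 replication factors 2 rose and 4 fell, of 30 repair genes 4 rose and 5 fell (4 and 6 adjusted over the list alone). Of 13 checkpoint factors 2 rose and 3 fell, and of 8 dNTP supply genes 3 rose and 1 fell (5 and 1).

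Heat shock genes moved in the same samples. hsp16 rose by 4.26 ± 0.25 (adjusted p = 4.8e-08), hsp104, a disaggregase, by 2.49 ± 0.26, psi1, a DNAJ co-chaperone, by 1.85 ± 0.21 and the mitochondrial chaperone hsp78 by 1.78 ± 0.21. Of 13 chaperones 11 rose, with a mean of 1.12 (adjusted p = 6.1e-11, and adjusted p = 0.051 with an estimated correlation). Of 22 stress genes 11 rose and 1 fell (adjusted p = 2.3e-06, and adjusted p = 0.24 with an estimated correlation). Proteasome genes rose in 6 of 26 (14 adjusted over the list alone; list adjusted p = 2.0e-05, and adjusted p = 0.051 with an estimated correlation). Redox genes rose in 3 of 12 (list adjusted p = 0.026, and adjusted p = 0.41 with an estimated correlation) and 1 of 13 glycolysis genes, pgi1, by 0.40 ± 0.10. On the lower side, 25 of 117 ribosomal protein genes fell (40 adjusted over the list alone; mean -0.32, adjusted p = 1.0e-13, and adjusted p = 0.42 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 14, led by rrp5 at -0.97 ± 0.11 (list adjusted p = 0.0015, and adjusted p = 0.14 with an estimated correlation). Iron uptake genes fell in 2 of 11, fio1 by 0.86 ± 0.15 and str1 by 0.74 ± 0.13, and iron-using proteins in 2 of 10. Mitosis and septation genes rose in 4 of 19. Mating genes rose in 3 of 23 and fell in 2, and ste6, an exchange factor for Ras1 in mating signalling, rose by 2.83 ± 0.26. Of 6 marker genes his3 rose by 0.31 ± 0.10.

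Over all genes 487 rose and 518 fell at 160 min in WT and chk1. With WT alone the count was 344 and with chk1 alone 492, and it was 650 and 658 without repeat 1 or 2. cdc22, cdc18, tos4, cdt2, cig2, cdt1, dut1, mik1, nrm1, spd1, hta1, rad16 and hsp16 kept their calls without either strain or repeat. The chk1 gene did not mark the strain in this condition, with -0.53 on the arrays labelled chk1 and -0.83 in WT with HU at 160 min, against -1.23 and -0.26 untreated.

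At 200 min the comparison rested on WT alone, and all histones rose. htb1, the H2B gene, was 3.31 ± 0.24 higher with HU (adjusted p = 8.2e-07, n = 1 strain with the spread taken from the other strains), hta2 3.21 ± 0.21, hhf1 3.10 ± 0.28 and hht1 2.71 ± 0.17. All 9 histones passed with a mean of 2.55 (adjusted p = 4.2e-19, and adjusted p = 0.039 with an estimated correlation). Of the 18 MBF targets 15 rose (16 adjusted over the list alone; mean 1.51, adjusted p = 4.5e-15, and adjusted p = 0.13 with an estimated correlation), among them cdc22 at 2.89 ± 0.56 (adjusted p = 0.0036), cig2 at 2.65 ± 0.29 and cdc18 at 2.03 ± 0.38, while cdt1 at 0.99 ± 0.55 did not pass. slp1 fell by 2.65 ± 0.65 (adjusted p = 0.016) and plo1 by 0.66 ± 0.16 (adjusted p = 0.014, lost without repeat 2). Of the mitosis list 3 of 19 and septation genes fell (5 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.58 with an estimated correlation). eng1 was at -2.21 ± 0.81 (adjusted p = 0.09).

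Stress genes were higher in 12 of 22 (16 adjusted over the list alone; mean 0.97, adjusted p = 6.8e-13, and adjusted p = 0.11 with an estimated correlation), but in 1 of 22 after quantile normalization. hsp16 was 4.63 ± 0.36 higher, the glutathione transferase gene gst2 1.91 ± 0.33 and the metallothionein gene zym1 1.59 ± 0.20. Redox genes rose in 4 of 12 as deposited and in 0 after quantile normalization (adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation). Proteasome genes rose in 4 of 26 (8 adjusted over the list alone; adjusted p = 2.3e-05, and adjusted p = 0.039 with an estimated correlation), and in 0 after quantile normalization. Chaperones rose in 2 of 13 (adjusted p = 0.010, and adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes fell in 26 of 117 (83 adjusted over the list alone, with 1 higher; mean -0.49, adjusted p = 3.6e-22, and adjusted p = 0.29 with an estimated correlation), led by rpl1603 at -1.74 ± 0.17, and ribosome biogenesis genes in 2 of 14. In the other lists, 3 dNTP supply genes rose, 3 repair genes rose (ctp1 by 1.38 ± 0.15), 1 replication factor rose and 3 fell. mrc1 rose by 1.18 ± 0.35, ste6 and map1 of the mating list rose, the heme protein gene cyc1 fell by 1.09 ± 0.17, and lys1 fell by 0.62 ± 0.13. Of 11 iron uptake genes str3 rose by 1.26 ± 0.25, where quantile normalization gave 1 lower gene instead, and 0 of 13 glycolysis genes passed limma's test, with tpi1 at -0.51 ± 0.18. In all 287 genes rose and 272 fell. The count was 280 without repeat 2, 243 after quantile normalization and 2065 with the matching chk1 arrays put back. mik1 (1.84 ± 0.53) and gas1 (-1.79 ± 0.50), a cell wall glucan enzyme, no longer passed without the chk1 conditions that contribute to the spread.

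In rad3 and cds1 cells at 160 min few G1/S genes passed the test while heat shock genes did. cdc22 was 0.73 ± 0.39 above untreated (adjusted p = 0.16, n = 2 strains) and cdc18 0.68 ± 0.27 (adjusted p = 0.058). Of 18 MBF targets 2 rose (1 adjusted over the list alone; mean 0.32, adjusted p = 0.28). hsp16 rose by 3.46 ± 0.25 (adjusted p = 1.7e-07), hsp104 by 2.87 ± 0.26, fes1, an Hsp70 exchange factor, by 2.48 ± 0.18 and hsp78 by 2.11 ± 0.21. All 13 chaperones rose as deposited and 7 after quantile normalization (mean 1.20, adjusted p = 8.8e-08, and adjusted p = 0.081 with an estimated correlation). Of 22 stress genes 15 rose and 2 fell (adjusted p = 1.4e-07, and adjusted p = 0.20 with an estimated correlation). Of 12 redox genes 7 rose and 2 fell (adjusted p = 0.028, and adjusted p = 0.44 with an estimated correlation), with the efflux transporter gene caf5 at 1.15 ± 0.12. Of 26 proteasome genes 16 rose (17 adjusted over the list alone, and 8 higher with 1 lower after quantile normalization; adjusted p = 0.00085, and adjusted p = 0.081 with an estimated correlation). All 9 histones rose, with a mean of 0.94 (adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation) and hta1 at 1.02 ± 0.18.

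Iron uptake genes were among those that fell in these 2 mutants at 160 min. The siderophore transporter genes str3 and str1 fell by 1.94 ± 0.18 and 1.68 ± 0.13, the high-affinity iron permease and oxidase genes fip1 and fio1 by 1.83 ± 0.19 and 1.80 ± 0.15, and the ferric reductase gene frp1 by 1.66 ± 0.16. Of 11 iron uptake genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; mean -0.98, adjusted p = 5.6e-06, and adjusted p = 0.081 with an estimated correlation). Ribosome biogenesis fell in 10 of 14 (adjusted p = 1.6e-05, and adjusted p = 0.081 with an estimated correlation) and ribosomal proteins in 41 of 117 with 1 higher (adjusted p = 3.1e-10, and adjusted p = 0.54 with an estimated correlation). Mitosis and septation genes rose in 6 of 19, among them mob1 of the septation initiation network by 0.89 ± 0.13 (list adjusted p = 0.026, and adjusted p = 0.82 with an estimated correlation). Replication factors fell in 8 of 37 and rose in 2, checkpoint factors rose in 4 of 13 and fell in 3, and repair genes rose in 10 of 30 and fell in 4. dNTP supply genes moved in 1 each way (ndk1 by 0.91 ± 0.10, spd1 by -0.92 ± 0.13), and iron-using proteins rose in 2 of 10 and fell in 1. Mating genes rose in 4 of 23 and fell in 5 as deposited, and rose in 4 and fell in 3 after quantile normalization. In glycolysis gpd3 rose by 0.69 ± 0.23, and lys1 of the marker genes fell by 0.39 ± 0.09. In all 1041 genes rose and 845 fell, and without cds1 the count was 846.

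At 200 min both mutants still held stress genes high. hsp16 was 3.28 ± 0.25 above untreated, gst2 2.81 ± 0.23, zym1 2.27 ± 0.14 and srx1, the sulfiredoxin gene, 1.37 ± 0.13. Of 22 stress genes 18 rose (19 adjusted over the list alone; mean 1.20, adjusted p = 2.0e-13, and adjusted p = 0.091 with an estimated correlation). Of 12 redox genes 9 rose and 1 fell (adjusted p = 2.3e-05, and adjusted p = 0.11 with an estimated correlation). Of 26 proteasome genes 19 rose (mean 0.39, adjusted p = 1.4e-07, and adjusted p = 0.019 with an estimated correlation). Of 13 chaperones 10 rose as deposited and 3 after quantile normalization (adjusted p = 2.2e-06, and adjusted p = 0.11 with an estimated correlation). Ribosomal protein genes fell in 83 of 117 with 1 higher (94 lower adjusted over the list alone; mean -0.52, adjusted p = 8.0e-20, and adjusted p = 0.29 with an estimated correlation). rpl1603 lay at -2.34 ± 0.12. Biogenesis genes fell in 9 of 14 (12 adjusted over the list alone), with gar2 at -1.56 ± 0.10. Iron uptake genes fell in 6 of 11 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.24 with an estimated correlation), with fio1 at -1.45 ± 0.15, and vht1, the biotin transporter gene, fell by 2.15 ± 0.15. Histones rose in 7 of 9 (8 adjusted over the list alone; mean 0.75, adjusted p = 4.8e-05, and adjusted p = 0.28 with an estimated correlation).

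The 2 mutants parted at 200 min in the cell cycle genes. cdc22 was 2.57 above untreated in rad3 and -0.36 in cds1, cdc18 1.91 and -0.02. eng1 was at 1.75 and -2.53, and the means of the 18 MBF targets were 1.15 and -0.20. The pooled values of cdc22 (1.10 ± 0.39, adjusted p = 0.04) and cdc18 (0.95 ± 0.27, adjusted p = 0.012) therefore rested on rad3, and without rad3 both lay below 0. Of the MBF targets 7 passed in the pooled comparison (adjusted p = 0.0051, and adjusted p = 0.59 with an estimated correlation), of 19 mitosis and septation genes 3, and of 37 replication factors 1 rose and 8 fell. In the other lists 4 of 13 checkpoint factors fell (rad26 by 0.73 ± 0.10; 2 fell after quantile normalization). There 6 of 30 repair genes rose and 3 fell, 2 dNTP supply genes rose, 4 mating genes rose and 3 fell, 2 glycolysis genes rose (gpd3 by 1.29 ± 0.23), lys1 fell by 0.82 ± 0.09. Of 10 iron-using proteins 1 rose and 2 fell as deposited and 2 rose and 1 fell after quantile normalization. In all 839 genes rose and 930 fell, and without rad3 the count was 1151 and without cds1 894.

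At 120 min the mutants showed the start of the same stress genes. hsp16 rose by 1.91 ± 0.25, hsp104 by 1.38 ± 0.26 and fes1 by 1.13 ± 0.18, and spd1 fell by 0.92 ± 0.13. Of 18 MBF targets 0 passed limma's test (list mean 0.10), with cdc22 at 0.28 ± 0.39. Stress genes rose in 2 of 22 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.58 with an estimated correlation). In all 16 genes rose and 14 fell. The count was 0 without cds1 (250 at an unadjusted p under 0.05), which ended all these calls, 17 without rad3, 12 without WT, 12 without chk1 and 6 without repeat 1.

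HU differences resembled each other more between strains late in the course than early. Over genes, which are not independent replicates, no pair of strains correlated above r = 0.270 at 40 or 80 min. At 120 min r was 0.256 to 0.466 among WT, rad3 and cds1. At 160 min it was 0.816 for rad3 and cds1, 0.750 for WT and chk1 and 0.528 to 0.646 for the other pairs. At 200 min it was 0.642 for rad3 and cds1, 0.612 for WT and cds1 and 0.495 for WT and rad3. Of the genes that rose at 160 min, 345 were shared by WT and chk1 (487) and by rad3 and cds1 (1041), where 103 would be shared by independent lists, and of those that fell 360 (88.8 for independent lists). At 200 min 216 risen genes were shared (48.9) and 185 fallen genes (51.3). These pairs share no cultures, but they share the reference and the estimate of the spread.

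**Figure D2:**
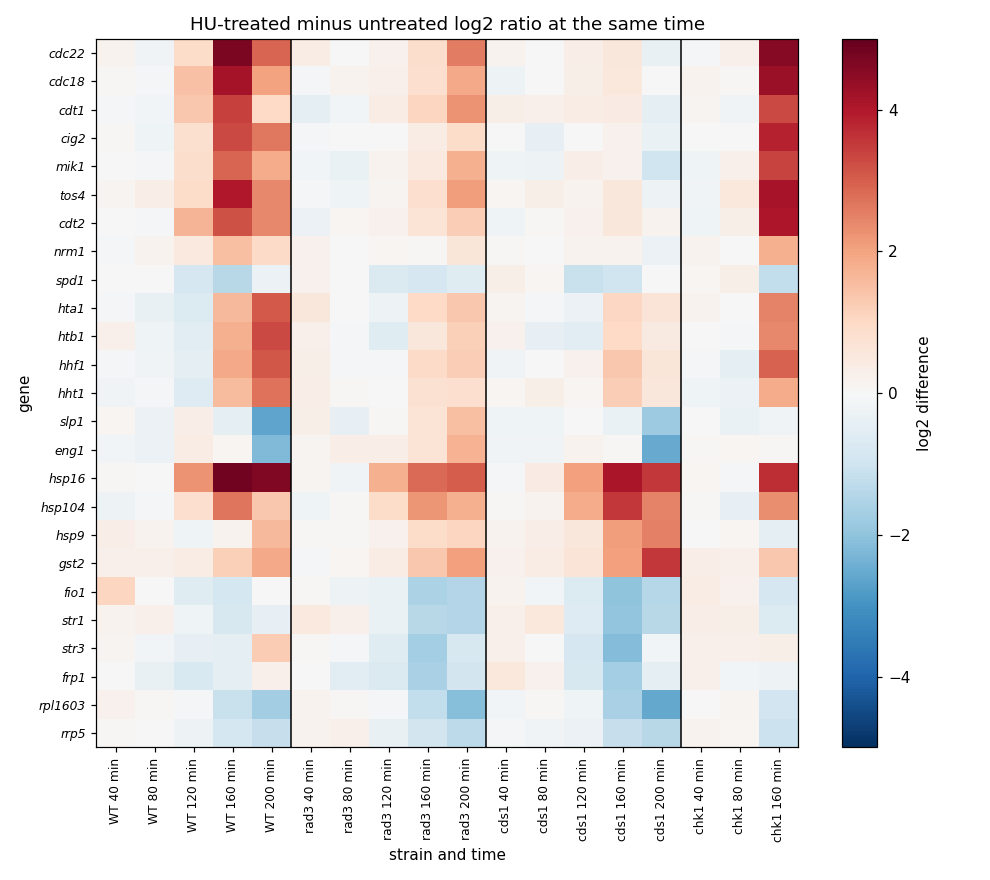
HU-treated minus untreated log2 ratio at the same time (colour, log2 units) for 25 genes (rows) by strain and time in min (columns), each cell being the difference of 2 condition means. cdc22 lies at 4.70 in WT and 4.56 in chk1 at 160 min against 0.88 in rad3 and 0.58 in cds1, while hsp16 lies between 2.85 and 4.83 in all 4 strains at that time.

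The difference between the strain pairs was then tested itself. At 160 min the HU effect in rad3 and cds1 minus that in WT and chk1 was -3.90 ± 0.56 for cdc22 (adjusted p = 0.00099, n = 2 strains on each side). It was -3.55 ± 0.38 for cdc18 (adjusted p = 0.0001), -3.38 ± 0.46 for tos4, -3.28 ± 0.29 for cig2 (adjusted p = 2.0e-05), -2.99 ± 0.28 for cdt2 and -2.73 ± 0.20 for ams2. Of 18 MBF targets 17 were lower, with a mean difference of -2.12 (adjusted p = 2.0e-30, and adjusted p = 0.059 with an estimated correlation). Of 9 histones 6 were lower (7 adjusted over the list alone; mean -0.81, adjusted p = 3.7e-07, and adjusted p = 0.30 with an estimated correlation). mik1 (-2.78 ± 0.53), cdt1 (-2.62 ± 0.55), dut1 (-2.71 ± 0.48), ste6 (-2.38 ± 0.37) and nrm1 (-1.52 ± 0.22) passed with all strains, and these 5 did not pass without chk1. mrc1 differed by -1.72 ± 0.35, ssb1 by -1.36 ± 0.28 and ctp1 by -1.38 ± 0.15.

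Iron uptake genes fell further in the mutant pair at 160 min, in 6 of 11 as deposited (7 adjusted over the list alone) and 3 after quantile normalization, with str3 at -1.85 ± 0.25 and fip1 at -1.33 ± 0.27 (mean -0.76, adjusted p = 2.6e-08, and adjusted p = 0.059 with an estimated correlation). Stress genes rose further in 5 of 22 as deposited, where quantile normalization gave 1 higher and 1 lower (adjusted p = 0.040, and adjusted p = 0.81 with an estimated correlation). hsp9 differed by 1.63 ± 0.39, the phosphatase gene pyp2 by 1.26 ± 0.22, ish1 by 1.17 ± 0.18 and caf5 by 1.16 ± 0.16. hsp9 did not pass without WT, cds1 or chk1, nor pyp2 and ish1 without chk1. hus1 of the checkpoint clamp was 0.81 ± 0.18 higher. Chaperones differed in 0 of 13 by limma (2 higher adjusted over the list alone), with a mean of 0.08 as deposited and -0.18 after quantile normalization. In all 143 genes were higher and 104 lower as deposited, and 37 higher and 70 lower after quantile normalization. The count was 40 without chk1, 73 without cds1, 113 without WT, 91 without repeat 1 and 133 without repeat 2.

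At 200 min, against WT alone, most histones differed. htb1 was at -2.49 ± 0.29 (adjusted p = 0.00037), hta2 at -2.20 ± 0.26, hhf1 at -2.19 ± 0.34 and hht1 at -1.99 ± 0.21. Of the histones 8 of 9 passed, or 2 after quantile normalization (mean -1.80, adjusted p = 2.5e-17, and adjusted p = 0.099 with an estimated correlation). cig2 was at -2.37 ± 0.35 (adjusted p = 0.0035). As deposited 5 of 18 MBF targets passed (13 adjusted over the list alone, and 0 over all genes after quantile normalization; mean -1.04, adjusted p = 6.2e-11, and adjusted p = 0.27 with an estimated correlation). That mean rested mostly on cds1, since the HU effects on the list were -0.20 in cds1, 1.15 in rad3 and 1.51 in WT. cdc22 at -1.79 ± 0.68 did not pass (adjusted p = 0.20). Iron uptake genes were lower in 4 of 11 (str3 -1.73 ± 0.31, lost without rad3 or repeat 2, and fio1 -1.46 ± 0.25) and 1 after quantile normalization. rgf3, a Rho1 exchange factor in septation, was 1.25 ± 0.22 higher and did not pass without rad3 or without repeat 2. The mitosis and septation mean was 0.73 higher (adjusted p = 2.7e-05, and adjusted p = 0.45 with an estimated correlation), which rested on rad3, with HU effects of 0.87 in rad3, -0.41 in cds1 and -0.50 in WT. In all 29 genes were higher and 46 lower as deposited, and 2 higher and 13 lower after quantile normalization. The count was 38 without chk1, 37 without repeat 1 and 26 without repeat 2. At 120 min limma called 0 genes for the difference (223 at an unadjusted p under 0.05), 4 with arrays as samples, 1 without chk1 and 5 with the matching arrays put back, and at 80 min 0 (106).

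Without HU many genes differed between the cds1 culture and WT. cds1 itself was 3.43 ± 0.13 lower (adjusted p = 1.5e-13, n = 6 times each), isp5, an amino acid permease gene, 2.27 ± 0.18 lower. ura4, a uracil synthesis gene widely used as an auxotrophic marker, was 1.74 ± 0.12 lower. The ammonium transporter gene amt1 and the proline permease gene put4 were 1.30 ± 0.11 and 1.28 ± 0.09 lower. gpd1 was at -1.22 ± 0.11 and atf1 at -1.05 ± 0.15, and 9 of 22 stress genes were lower and 2 higher (12 called adjusted over the list alone). The hexose transporter gene ght5 was 1.16 ± 0.18 higher, the zinc transporter gene zrt1 1.01 ± 0.16 and the helicase-nuclease gene dna2 0.52 ± 0.08. Repair genes were higher in 12 of 30 and lower in 3 (17 called adjusted over the list alone; nth1 0.80 ± 0.14, rad50 0.48 ± 0.10). Replication factors were higher in 7 of 37 and lower in 1, mitosis and septation genes lower in 5 of 19 and higher in 1 (slp1 -0.74 ± 0.16, plo1 -0.39 ± 0.08). Ribosomal proteins were lower in 52 of 117 and higher in 3 (58 called adjusted over the list alone), glycolysis genes lower in 7 of 13 (8), iron-using proteins lower in 6 of 10, redox genes lower in 4 of 12 and chaperones lower in 4 of 13 (3). Mating genes were higher in 6 of 23 and lower in 3 (10 adjusted over the list alone), ribosome biogenesis higher in 4 of 14 and lower in 2 (7), checkpoint factors and MBF targets higher in 2 and lower in 2 each, and proteasome genes likewise (4, 3 and 0 adjusted over the list alone). Further, 2 dNTP supply genes, 3 marker genes, 1 iron uptake gene (0 adjusted over the list alone) and 1 histone were lower. That histone, hht2, was at 0.02 without repeat 2 (adjusted p = 0.92) and did not pass after quantile normalization (adjusted p = 0.15). In all 877 genes were higher and 961 lower. With the second array repeats left out the count was 330. The differences between the 2 WT repeats correlated between WT conditions with a median r of 0.629, so they held a part common to the times. Such a part can enter the contrast with WT at every time. The p-values over times do not measure it, and strain cannot be told from array batch here.

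In rad3 cells without HU some stress genes lay above WT and some ribosomal protein genes below it. rad3 itself was 2.27 ± 0.10 lower (adjusted p = 9.9e-13, n = 6 times each), hsp9 was 1.41 ± 0.24 higher, zym1 1.25 ± 0.17, ddr48 1.14 ± 0.16 and hsp16 1.68 ± 0.42 (adjusted p = 0.021, lost without 120, 160 or 200 min). Stress genes were higher in 4 of 22 (7 adjusted over the list alone), ribosomal proteins lower in 43 of 117 (92). Glycolysis genes were lower in 5 of 13 as deposited and 1 after quantile normalization (10), iron-using proteins lower in 4 of 10 (6), ribosome biogenesis lower in 2 of 14 (5). Mating and meiosis genes were higher in 3 of 23 and lower in 1 (4), with the meiotic transcription factor gene mei4 at 0.61 ± 0.14. MBF targets passed in 0 of 18 by limma, with cdc22 at -0.19 ± 0.27. In all 131 genes were higher and 269 lower as deposited, 171 and 223 after centring, and 152 and 138 after quantile normalization. The count was 87 to 211 with 1 of the times from 40 to 200 min left out (87 without 40 min, 96 without 160 min, 141 without 120 min, 189 without 200 min and 211 without 80 min), 800 without 0 min, 2632 without repeat 1 and 1268 without repeat 2. Without repeat 2 the lower values of rip1 (-0.60 ± 0.09), rps001 (-0.57 ± 0.11), fib1 (-0.55 ± 0.10), gln1 (-0.64 ± 0.14), rpl1602 (-0.60 ± 0.13) and shm1 (-0.60 ± 0.09) did not pass, and the last 2 lay above 0.

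In chk1 cells without HU chk1 itself was 0.96 ± 0.12 lower than in WT (adjusted p = 0.00034, n = 6 times each, 1 of them the matching 120 min arrays). isp5 was at -1.43 ± 0.18, tps3 at -1.10 ± 0.21, isp7 at -0.87 ± 0.13, ste11, the mating transcription factor gene, at -0.72 ± 0.13 and ura4 at -0.65 ± 0.12, with atf1 at -0.76 ± 0.15 (lost after quantile normalization). On the upper side the kinetochore gene spc24 was at 0.50 ± 0.14, which did not pass without repeat 2 or without 40, 80 or 160 min. Stress genes were lower in 5 of 22 and higher in 1 (7 called adjusted over the list alone), ribosomal proteins lower in 15 of 117 (58), or 5 after centring and 1 after quantile normalization. Iron-using proteins were lower in 5 of 10, or 2 after centring and 0 after quantile normalization, chaperones lower in 3 of 13 (9 adjusted over the list alone) and mating genes lower in 3 of 23 and higher in 1 (7). Redox genes were lower in 2 of 12 (4) and glycolysis genes in 1 of 13 (6), each in 0 after quantile normalization. In all 59 genes were higher and 285 lower as deposited, 150 and 150 after centring, and 77 and 64 after quantile normalization. Without the matching arrays 410 were higher and 425 lower. The count was 76 without 80 min, 86 without 160 min, 92 without 40 min, 159 without 200 min, 597 without 120 min, 198 without 0 min, 1231 without repeat 1 and 214 without repeat 2. All 3 mutant comparisons use the same WT conditions, so the limit from the WT repeats given for cds1 holds for each of them.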

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

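Every test of an explanation described here was chosen after the result it concerns was seen.

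The difference in HU effect between rad3 and cds1 on one side and WT and chk1 on the other was marked at 3 times because limma called genes in it, namely 2 genes at 40 min, 247 at 160 min and 75 at 200 min, where WT stood alone. At 200 min the 19 mitosis and septation genes moved in opposite ways in the 2 mutants, by 0.87 in rad3 and -0.41 in cds1 on average with HU against without, and this difference between the 2 mutants was not tested for significance because each has 1 culture per arm. The checkpoint factors without HU at 80 min averaged -0.37 in rad3, which lay far from the other 3 strains. That list includes the mutated gene rad3 itself, and over the 12 others the mean was -0.16 in rad3 against -0.11 in WT, -0.10 in cds1 and -0.09 in chk1. The first value was 1 of 96 groups examined in this way, where about 4.8 would stand apart by chance.

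The match of 6 arrays labelled chk1 with WT arrays was weighed first. The differences between the 2 repeats of these chk1 conditions correlated at 0.910 or more with those of the same WT conditions, while 2 different WT conditions reached at most 0.771. This would be seen with 1 hybridisation listed under both strains. It largely follows from the closeness of the arrays themselves and is no separate support. Separate cultures with close expression would not give second repeats that differ with an SD of at most 0.00594, since repeats of a single condition differed more in every strain. That SD was at least 0.319 in WT and 0.069 in cds1, with a median of 0.0789 in chk1. The first repeats differed with an SD of 0.110 to 0.184, which overlaps the repeats of cds1 (0.069 to 0.152). For them the SD alone does not decide. On the 50 genes that differ most between chk1 and WT elsewhere, the matching WT conditions scored at most -1.40, below all other chk1 conditions (-0.14 to 1.87), so the shared values look like the other arrays labelled WT. Repeat differences of the matching chk1 conditions correlated with those of other WT conditions at a median r of 0.599. With those of other chk1 conditions the median r was 0.00136, which also argues for arrays of the WT batch. Both comparisons rest on differences between WT and chk1 arrays that may come from strain or from array batch. They therefore do not tell WT cells from chk1 cells hybridised with the WT batch. The chk1 gene taken alone does not settle it. In the matching conditions it was at -0.74 untreated at 120 min, -0.50 with HU at 120 min and -0.79 with HU at 200 min on the arrays labelled WT, and at -1.12, -0.42 and -0.94 on those labelled chk1. Other WT conditions ran from -0.83 to 0.16 and other chk1 conditions from -1.55 to -0.53, the last being HU at 160 min, where WT was lower (-0.83).

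The high stress genes at 0 min were weighed second. A wider scale of the 0 min arrays does not account for them, because the fall from 0 to 40 min in units of each array's SD was still at least 1.73, with an SD over strains of 0.477. Ribosome biogenesis genes lay lower at 0 than at 40 min in all 4 strains, by a difference of -0.59 or further below 0, which is consistent with a stress-like state of the cells at the start. A change of medium, temperature or handling during elutriation could also give this and was not tested.

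The opposite septation genes at 200 min were weighed last. In these cultures the HU-treated levels differed by 1.18 ± 0.206 (SE over 19 genes, rad3 minus cds1). The untreated levels differed by -0.09 ± 0.0584. The contrast thus lay in the HU-treated values rather than in different positions of the untreated cultures. After quantile normalization the difference in HU effect was still 1.08 ± 0.187, so array scale alone did not give it. Genes of 1 culture are not independent replicates, and the SE over genes does not measure the spread between cultures. The HU effect on this list in WT at 200 min, given above, lay close to that in cds1 and opposite to that in rad3. An earlier entry of rad3 cells into mitosis and a later timing of the cds1 culture with HU may both fit. With 1 culture per arm these values do not separate them.

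The counts of genes were also compared with those from other groupings of the same conditions. For the mean HU effect in each strain the real count is 0, which every grouping reaches, so these comparisons say nothing on chance: 16 of 16 in WT, 16 in rad3, 16 in cds1 and 16 in chk1, with highest other counts of 0, 5, 0 and 0. The same holds for rad3 minus WT, cds1 minus WT, chk1 minus WT and the contrast of the strain pairs, with a real 0, 100 of 100 groupings each and highest other counts of 0, 3, 127 and 2. These groupings mix the time points, so a grouping can set late times mostly against early ones. Whether that gave the 127 for chk1 minus WT was not tested. Without HU, 2 of 32 groupings reached the 400 genes of rad3 minus WT, the highest other being 497, so a grouping by chance is not excluded there. For cds1 minus WT it was 1 of 32 (1838 against 56 at most in the others) and for the time course 1 of 100 (3952 against 224). For chk1 minus WT it was 1 of 32 (344 against 215). There the untreated condition that matches WT arrays holds close values under both labels. Exchanging it gives nearly the same grouping, so the 32 are not all distinct. A grouping by chance is therefore not excluded for chk1 minus WT either.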

How the results depend on the processing

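All tests by time point, and the settings that leave out or put back the matching arrays, were chosen after the planned results were seen. Of 480 counts of genes under other settings 342 stayed within a factor of 1.5 and 138 moved. Of 456 list results 397 were unchanged, 54 weaker, 4 stronger and 1 reversed. Of 10963 values of named genes 10295 were unchanged, 453 weaker, 202 stronger and 13 reversed. Among the 64 called named genes of the planned comparisons, leaving out a repeat, time or strain kept 494 of 576 calls, lost 78 and reversed 4, and other settings kept 527 of 563 and lost 36. Among the 172 of the comparisons by time, 927 of 1144 calls were kept, 215 lost and 2 reversed, and other settings kept 1418 of 1542 and lost 124. Unless construction is named, the cause was not tested.

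The replicate block and pairing were examined as follows. Repeat differences with and without HU correlated at 0.459 to 0.739 in WT, -0.0975 to 0.320 in rad3, -0.0118 to 0.212 in cds1 and -0.0312 to 0.293 in chk1, so repeat numbers pair in WT only. With each array as a sample and no block, which by construction counts technical repeats as independent, the mean HU effect called 197 genes in WT, 759 in rad3, 1100 in cds1 and 580 in chk1, cds1 minus WT called 1, the contrast of the strain pairs 155 and late minus early 185. With a replicate block these were 210, 784, 1128, 614, 1, 165 and 195. Without HU, rad3 minus WT gave 794 and chk1 minus WT 785 without a block, and 796 and 791 with it. By time without a block, WT and chk1 gave 1 at 40 min, WT 93 at 120 min and 969 at 200 min, rad3 and cds1 13 at 40 min and 181 at 120 min, and the difference 0 at 40 min (395 at an unadjusted p under 0.05 by limma), 4 at 120 min, 654 at 160 min and 393 at 200 min. With the block these were 1, 100, 1001, 20, 189, 8, 4, 683 and 421, and WT and chk1 at 80 min gave 3. The block changed no other count beyond a factor of 1.5. With the condition as a random block (correlation within conditions 0.342 with HU and 0.257 without) the mean HU effect gave 36, 212, 565 and 169, the contrast of the pairs 13, late minus early 42, WT at 120 min 10, rad3 and cds1 at 40 min 1, and the difference 0 at 40 min (105 by limma at an unadjusted p under 0.05) and 1 at 120 min.

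Late times alone gave 10 genes in WT, 140 in rad3, 651 in cds1 and 28 in chk1. Quantile normalization gave 28 for the mean effect in cds1, 2 for late minus early, 141 for chk1 minus WT without HU, 6 for WT at 120 min, 243 for WT at 200 min, and 1, 107 and 15 for the difference at 40, 160 and 200 min. Centring gave 2 for late minus early and 9 for WT at 120 min. Trend and robust settings gave 1 for WT at 120 min, 8 for rad3 and cds1 at 120 min and 1 for the difference at 40 min, and no filter on missing values also gave 1 there. The spread from WT alone gave 0 for late minus early (521 at an unadjusted p under 0.05 by limma). Without the 0 min start, rad3 minus WT called 800, chk1 minus WT 198 and the time course 2516. Estimated correlations between genes left 0 of the planned list calls.

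Without the arrays with shifted medians, chk1 minus WT gave 764, WT at 120 min 4 and the difference at 40 min 1. Without the matching chk1 arrays, late minus early gave 6 and chk1 minus WT 835. With them put back, matching arrays are by construction counted under both strains. WT then gave 375 at 120 min and 2065 at 200 min, rad3 and cds1 10 at 40 min and 53 at 120 min, and the difference 5 at 120 min and 698 at 200 min.

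Leaving out 1 repeat, time or strain gave these lowest and highest counts. The mean HU effect in rad3 ran from 0 to 133 (limma, 872 at an unadjusted p under 0.05 without repeat 1) and late minus early in WT from 0 to 225. Without HU, rad3 minus WT ran from 87 to 2632, cds1 minus WT from 330 to 2632 and chk1 minus WT from 76 to 1231. By time, WT and chk1 ran from 0 to 4 at 40 min and 344 to 985 at 160 min, and WT from 7 to 17 at 120 min and 280 to 576 at 200 min. rad3 and cds1 ran from 0 to 21 at 40 min, 0 to 27 at 120 min, 846 to 1820 at 160 min and 894 to 1694 at 200 min. The difference ran from 0 to 5 at 40 min, 0 to 1 at 120 min, 40 to 173 at 160 min and 26 to 98 at 200 min.

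Some values changed sign. Ribosomal proteins in cds1 minus WT with HU pointed the other way with late times alone and were called there (camera in limma, adjusted p = 0.00586, against adjusted p = 0.18 with all times). Each of the following is given as the lowest and highest value with 1 repeat or strain left out. Over repeats, rad3 minus WT without HU ran from -1.33 to 0.13 for shm1, -1.47 to 0.28 for rpl1602 and -0.28 to 0.50 for suc22, and cds1 minus WT from -0.34 to 2.19 for SPOM_SPBP22H7.04 and -0.53 to 0.019 for hht2. Over strains, the HU effect on the chk1 gene at 160 min ran from -0.57 in WT alone to 0.70 in chk1 alone. At 200 min in rad3 and cds1 it ran from -0.36 to 2.57 for cdc22, -0.017 to 1.91 for cdc18, -0.49 to 2.24 for cdt1, -0.98 to 1.78 for mik1 and -0.56 to 0.89 for cdc15, the lower value being without rad3, and from -2.53 without rad3 to 1.75 without cds1 for eng1. The difference for cdt1 at 200 min ran from -1.48 without rad3 to 1.25 without cds1.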

Other observations

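The tests weighed here were chosen after the results were seen.

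A few genes chosen after their values were seen add to the time course without HU. str3, a siderophore transporter gene, had its highest mean at 160 min (2.14 ± 0.20, SD, n = 4 strains), and the stress kinase gene srk1 and the glutathione peroxidase gene gpx1 began at 3.32 and 3.85 at 0 min. rev1, the translesion polymerase gene, was 1.85, 2.81 and 1.71 higher with HU at 120, 160 and 200 min in WT and 1.12 higher in chk1 at 160 min.

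By median r, array repeats were closest in chk1 (0.986, against 0.976 in cds1), with the 2 repeats of HU at 160 min holding 77.1% identical values. The lowest correlation between repeats was 0.509 in WT, 0.398 in rad3, 0.936 in cds1 and 0.698 on arrays labelled chk1. That last value belongs to untreated 120 min, a condition that matches WT arrays. Among chk1 conditions that do not match, the lowest was 0.954, untreated at 200 min.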
